A study of Mus musculus with 6 samples.

How the data were processed

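RNA sequencing compared primary mouse epidermal keratinocytes transfected with a control small RNA (3 libraries) or with pro-miR-148a (3 libraries). Groups were taken from the treatment label of each sample. What was deposited for the series and used here is a table of the authors' own comparison and a table of GO categories; neither has a column per library. DESeq2 and the mouse build mm9 are named, per the submitters' processing notes, with no version or role. The aligner, the read counter and the transcript annotation are not given in the sources used here.

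Per the file headers, the authors' expression table gives for each RefSeq transcript a base mean (a signal: the mean normalized count over the libraries compared), a log2 fold change, its standard error, a Wald score (the log2 fold change divided by its standard error, which held to within 1.69e-07 in all 17845 transcripts with values), a p-value and an adjusted p-value. The authors' adjusted p-values equal a Benjamini-Hochberg adjustment of the p-values over the 11757 transcripts that have one, to within a relative difference of 0.00885. The 6088 transcripts with a fold change and no adjusted p had base means up to 3.56, and those with one had base means of 3.56 or more, so transcripts with low counts were filtered by mean. The standard error never exceeded 0.39, also at base means under 1, as in a fit that shrinks fold changes toward 0; folds of weakly counted transcripts are then understated. The median standard error was 0.08 at base means of 1000 or more and 0.37 at base means under 100. The GO table of the authors holds, per the file headers, the number of changed genes and of all genes per category and p-values of over- and under-representation with adjusted p-values; the authors' choice of changed genes is not given in the sources used here. Library totals are unknown, so no counting interval is given for any gene.

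Because no counts or values per library could be used, no differential test was run here, and the authors' adjusted p at 0.05 stands in for a test of each gene. Transcripts were paired with gene symbols through their RefSeq accessions (42739 of 42885 matched, GRCm38.p6 annotation). Each gene was represented by its tested transcript with the highest base mean, giving 11038 genes. As mm9 and the annotation used here differ in build, no genomic coordinates are given and genes are identified by RefSeq accession.

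The table does not name the numerator of its fold changes. Its sign was turned after the site test, as described with the results, so that positive values are higher with miR-148a. For that test the longest annotated 3' UTR of each gene (GENCODE M21, at least 20 bases) was searched for TGCACTG, TGCACTGA, GCACTGA, GCACTG and AGAACTT in 9728 genes, and the difference of median log2 fold changes was taken with a bootstrap interval (95%, 2000 resamples of genes) and a permutation test (100000 permutations). A rank regression on UTR length, GC content and base mean was added after seeing the data, to score all 15616 heptamers found in at least 100 genes.

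Gene lists (35) were fixed before the data were examined, and 31 had at least 5 tested genes. A list's median was set among 10000 random lists matched on mean expression in 20 bins, two-sided (smallest p 0.0002), with Benjamini-Hochberg adjustment over the 31 lists; 7 passed, 2 of them higher and 5 lower, and 1 of the 7 is not reported here. These p-values treat genes as independent and are too small where genes of a list vary together; a correlation between genes could not be estimated without values per library. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the authors' p-values of the list's members. The lists, the site test and the rule for naming genes were fixed together. The rule names Rock1, Elf5, Dnmt1 and Mir148a, the 10 highest and 10 lowest log2 fold changes past an adjusted p of 0.05 with a base mean of at least 100 and no predicted gene name, up to 4 changed members per list (or, where fewer than 2 passed, its 2 most abundant), and the 5 most abundant genes with an 8mer that fell. The rule's condition on replicate overlap could not be applied. Further members of lists (Cnfn, Krt1, Krt10, Lor, Ivl, Ppl, Krt78, Krt5, Krt6a, Krt17, Cxcl5, Defb14, Ccna2, Insig1, Met, Klf4, Mki67, Mcm3, Eno1, Hk2, Col1a1, Col1a2, Rock2) and Krt6b, Krt7, Klk10, Arg1, Trp63 and Krt14 were chosen after their values were seen.

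The list test, the heptamer score and a recentred Wald test were tested on simulated data. Of 200 random lists, 6.5% had p under 0.05, and of 200 lists of 20 genes shifted by 0.5, 98.0% did. All 20 planted heptamers ranked first. Their planted shift was larger than the site differences reported here, and it was put on shuffled fold changes. The simulation therefore does not show how the score behaves at the observed size, or with trends in UTR length, GC content or expression. The recentred Wald test found 69.5% of 200 genes changed by 1 on the log2 scale, and 4.79% of its calls were false. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.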

Results

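Primary mouse epidermal keratinocytes, the cells that build the outer layer of the skin, were isolated from newborn C57BL/6 pups. The medium had 0.05 mM calcium, a low concentration that holds these cells in a proliferative, little-differentiated state. They were transfected either with a control small RNA or with pro-miR-148a, which raises the level of the microRNA miR-148a, at 200 nM. RNA was collected 48 h later for RNA sequencing. The labels list 3 libraries of each of the 2 groups and do not say whether these came from separate cultures or animals. The p-values may therefore measure technical spread. The comparison asked which transcripts differ after miR-148a is raised. The data analysed here are the authors' deposited table of that comparison, with 42885 RefSeq transcripts, and their table of gene ontology (GO) categories. The expression table holds no value per library, so the depth of each library is unknown and the errors below are the authors' standard errors (SE) of the log2 fold change. Its base means, the authors' mean normalized counts, add up to 2.65e+07 per average library. In all, 25040 transcripts (58.4%) were listed at 0, and 11757 transcripts of 11038 named genes had an adjusted p-value.

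Genes whose 3' untranslated region (UTR) carries a site for miR-148a lay to one side of the other genes, and this set the direction in which the table is read. The authors' deposited table does not say which group is the numerator of its fold changes. The seed of miR-148a-3p, bases 2 to 8 of the microRNA, pairs with TGCACTG (a 7mer-m8 site), and the same site followed by A is an 8mer. MicroRNAs lower the transcripts they pair with, and genes with such sites had higher values as deposited. The deposited values are therefore read here as control over miR-148a, in the order of the words in the table's title. All signs below are turned so that a positive log2 fold change is higher with miR-148a. Every direction in this text rests on that reading and would turn together with it. The site test is therefore no independent evidence that targets fell.

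In this orientation, the 1543 genes with a 7mer-m8 site had a median log2 fold change of -0.07, against 0.01 for the 8185 genes without one. The difference was -0.08 (95% bootstrap interval over genes -0.10 to -0.04, two-sided permutation test p = 1e-05, the smallest that 100000 permutations can give). Genes are not independent replicates, so this p describes the gene set in these libraries. Sorted by their best site, 425 genes with an 8mer lay 0.12 below the 5931 genes with no site (-0.12, interval -0.15 to -0.08). The 1118 genes with a 7mer-m8 differed from them by -0.06 (-0.10 to -0.03), 664 genes with a 7mer-A1 (GCACTGA) by -0.06 (-0.10 to -0.02), and 1590 genes with a 6mer alone by 0.00 (-0.0043, interval -0.036 to 0.023). These classes were not matched on UTR length. Its median was 807 bases in genes with no site, 1924.5 with a 6mer alone, 2327.5 with a 7mer-A1, 2506 with a 7mer-m8 and 2378 with an 8mer. By the adjusted p of the authors' deposited table, 120 of the genes with an 8mer fell (28.2%) and 50 rose (11.8%), against 17.2% and 18.4% of the genes without one. Of the genes with a 7mer-m8 site, 340 fell (22.0%) and 226 rose (14.6%), against 16.9% and 18.7% of those without. A site in a single gene is therefore no evidence that its change is direct. Sites are named below for only some of the genes that carry one. Among the 630 heptamers of the same base composition the site ranked 26th from the most negative difference, and 16th among the 578 of them found in at least 100 genes. The difference was smaller for the site of the passenger strand miR-148a-5p, AGAACTT (-0.04, interval -0.07 to -0.01, 1553 genes). After the rank regression on UTR length, GC content and base mean, AGAACTT ranked only 1479th of 15616 heptamers from the lowest (z = -1.15). The unadjusted difference is therefore no evidence of repression by the passenger strand.

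**Figure D1:**
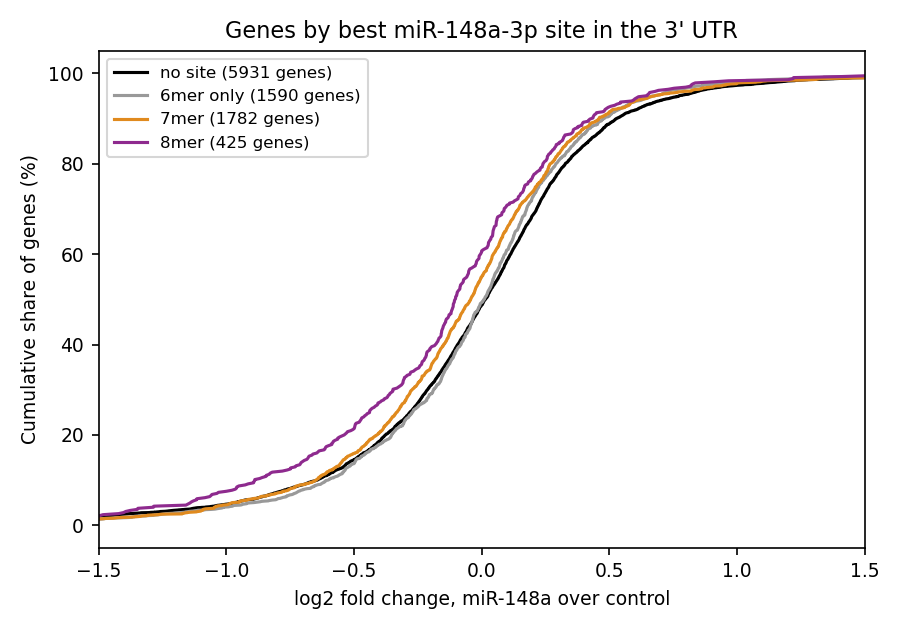
Cumulative share of genes (y axis, percent) against log2 fold change, miR-148a over control (x axis), for genes grouped by the best miR-148a-3p site in their longest annotated 3' UTR; each line is one group and 7mer joins the m8 and A1 kinds. The line for the 425 genes with an 8mer lies to the left of the line for the 5931 genes with no site, with medians of -0.10 and 0.01.

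Rock1, the gene of a kinase that drives actomyosin contraction and a known target of miR-148a, was lower with miR-148a in the authors' deposited table, by 1.20-fold (log2 fold change -0.26 ± 0.09 SE, adjusted p = 0.0106, NM_009071, base mean 2780). The longest 3' UTR of Rock1 has 1647 bases and 1 7mer-m8 site that starts at base 895, counted from 1 at the first base of the UTR. The related kinase gene Rock2 had a log2 fold change of 0.04 ± 0.06 SE in the authors' deposited table and did not pass the test (adjusted p = 0.694). Elf5, an ETS-family transcription factor with an 8mer at base 1034 of 1329, could not be compared: both of its transcripts (NM_010125 and NM_001145813) were listed at 0 in the authors' deposited table. Dnmt1, the maintenance DNA methyltransferase, has an 8mer at base 23 of 312. Of its 5 transcripts 3 were listed at 0 and the others had base means of 1.96 and 0.167 in the authors' deposited table, with no adjusted p. The row of the Mir148a gene itself (NR_029719) had a base mean of 0.161 in the authors' deposited table, and it does not measure the transfected small RNA. Genes with several RefSeq transcripts were often listed at 0: 34.5% of the transcripts of genes with 1 transcript in the table, and 73.9% of those of genes with 2 or more. For the latter a value describes the transcript listed and may not stand for the gene, and a value at 0 is not a measurement of absence. Of the genes with fold changes below, Krt19, Kdr, Flt1, Pkm and Cnfn have 2 transcripts in the table and Mbp has 8.

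Among miR-148 family targets known from the literature, 10 of 32 tested genes fell, 4 rose and 18 did not pass the test, with the same counts adjusted over the list alone. In the authors' deposited table Itgb8, the integrin beta 8 subunit, fell 1.89-fold (log2 fold change -0.91 ± 0.15 SE, adjusted p = 2.12e-08). Gadd45a, a stress-response gene with an 8mer, fell 1.81-fold (-0.86 ± 0.12 SE), and the Wnt ligand gene Wnt10b, at a base mean of 26.0, fell 2.56-fold (-1.36 ± 0.37 SE, adjusted p = 0.00133) in the authors' deposited table. The 4 that rose were Ccna2 (1.77-fold), Insig1 (1.45-fold), Met (1.34-fold) and Klf4 (1.19-fold) in the authors' deposited table. The median of the list, -0.12, did not stand apart from random lists matched on mean expression (adjusted p = 0.197 over 31 lists). The most abundant genes with an 8mer that fell in the authors' deposited table were S100a11 (-0.22 ± 0.05 SE), Idi1 of the cholesterol pathway (-0.59 ± 0.08 SE), Arl6ip1 (-1.06 ± 0.07 SE), Ajuba (-0.16 ± 0.06 SE) and Jmy (-0.36 ± 0.08 SE).

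By the authors' adjusted p, 3745 transcripts differed between the groups, 31.9% of those tested, of which 1859 were higher and 1886 lower with miR-148a. Counted as genes, each by its most abundant tested transcript, 1844 rose and 1856 fell, and changes of more than 2-fold were less even, with 255 genes higher and 495 lower in the authors' deposited table. The gene with the highest log2 fold change at a base mean of 100 or more was Krt19, a keratin of simple epithelia and of hair follicle cells, at 15.5-fold higher (log2 fold change 3.95 ± 0.16 SE, adjusted p = 2.4e-130, authors' deposited table). Id2, an inhibitor of helix-loop-helix transcription factors, rose 6.77-fold (2.76 ± 0.07 SE, base mean 5100), with an adjusted p listed as 0 in the authors' deposited table. Crnn, the squamous epithelial protein cornulin, which itself carries an 8mer, rose 7.64-fold in the authors' deposited table. Psca, a cell surface antigen, rose 5.95-fold and Edn2, the peptide endothelin 2, 7.81-fold in the authors' deposited table. The other genes of this group were Pllp (9.52-fold), Lrrc26 (6.66-fold), the VEGF receptor gene Kdr (6.65-fold), the hair keratin-associated Krtap3-2 (6.02-fold) and Sprr2j-ps (5.90-fold) in the authors' deposited table. Sprr2j-ps is a pseudogene whose reads may be shared with its small proline-rich relatives.

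At the other end, Mmp13, a collagenase, was 15.7-fold lower with miR-148a (log2 fold change -3.97 ± 0.23 SE, adjusted p = 8.6e-67, authors' deposited table), and Lcn2, the antimicrobial lipocalin, was 11.1-fold lower (-3.47 ± 0.16 SE). The proton pump gene Atp12a fell 9.77-fold, Nrk 9.27-fold, Nat8l, which carries an 8mer, 8.83-fold, and Chil1 7.72-fold in the authors' deposited table. Krt77, a keratin of suprabasal and sweat duct cells, fell 7.79-fold and Npl 7.59-fold in the authors' deposited table. The cornified layer protease inhibitor Cst6, at a base mean of 17625, fell 7.43-fold and Krt79, a keratin of the hair canal, 6.67-fold in the authors' deposited table. Fold changes of weakly counted transcripts are pulled toward 0 in this table: the 3418 transcripts with a base mean under 1 reached at most 0.25 in size.

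**Figure D2:**
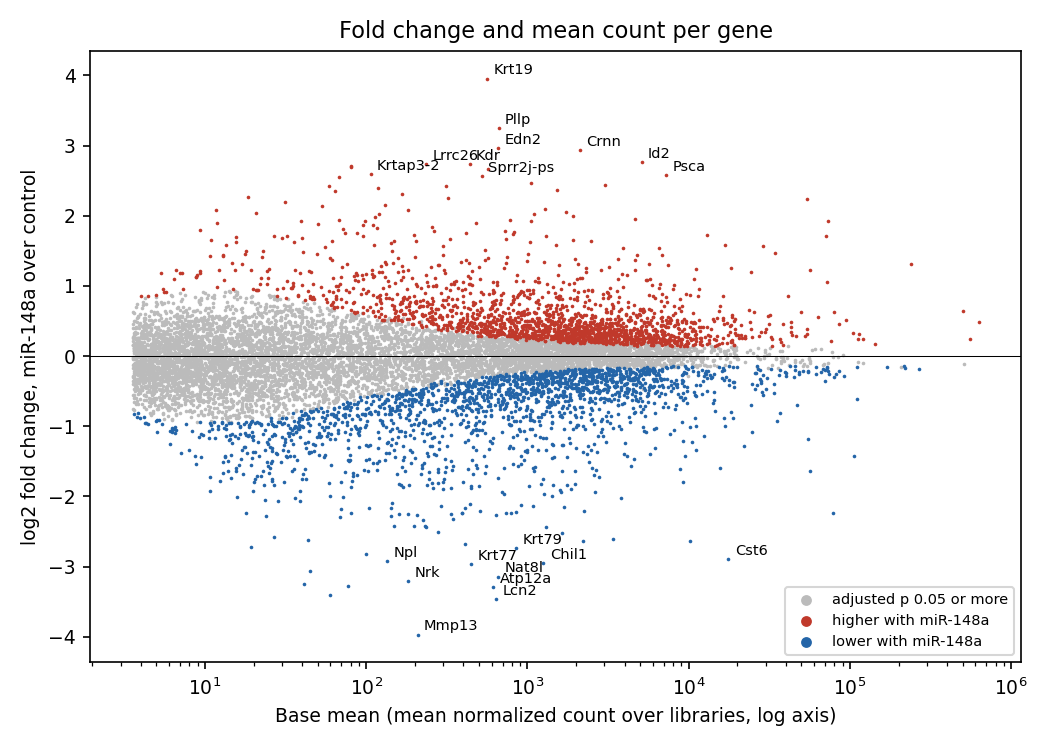
Log2 fold change, miR-148a over control (y axis), against base mean on a log axis (x axis) for 11038 genes, each by its most abundant tested transcript; red and blue points have an adjusted p under 0.05 and grey points do not. The 20 labelled genes run from Krt19 at 3.95 to Mmp13 at -3.97.

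Genes of the dividing cell rose together. Of 26 tested genes of the proliferation list, 22 rose, none fell and 4 did not pass the test (23 rose when adjusted over the list alone). Their median was 1.67-fold higher with miR-148a (log2 0.74, above all 10000 random lists, adjusted p = 0.00124 over 31 lists). In the authors' deposited table the mitotic regulators Foxm1 (log2 fold change 1.30 ± 0.10 SE), Plk1 (1.26 ± 0.10 SE, with a 7mer-m8 site), Ube2c (1.17 ± 0.08 SE) and Ccnb1 (1.15 ± 0.08 SE) rose most. The proliferation marker Mki67 rose by 1.71-fold and the replication helicase gene Mcm3 by 1.60-fold in the authors' deposited table. Cdkn1b, an inhibitor of cyclin-dependent kinases with a 7mer-A1 site, fell 1.46-fold (-0.55 ± 0.07 SE, adjusted p = 4.55e-15, authors' deposited table). It belongs to the list of p53 targets and cell cycle inhibitors, in which 7 of 24 genes rose and 4 fell. Whether it bears on the proliferation genes was not tested. Genes of glycolysis and the hypoxia response also lay higher: 11 of 20 rose, 1 fell and 8 did not pass (the same counts adjusted over the list alone), with a median of 0.40 (adjusted p = 0.00124; 0.61 over genes with a base mean of at least 100). In the authors' deposited table Eno1 rose 1.54-fold, Pgk1 1.55-fold, Pkm 1.79-fold and the mitophagy gene Bnip3 1.65-fold. Hk2, a hexokinase, fell 1.44-fold in the authors' deposited table.

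Genes of the differentiated epidermis were mostly lower with miR-148a. Of 37 tested genes of suprabasal and cornified keratinocytes, 20 fell, 9 rose and 8 did not pass the test (the same counts adjusted over the list alone), with a median log2 fold change of -0.36 (below all random lists, adjusted p = 0.00124) and a mean of -0.56. The desquamation proteases Klk5 (-2.64 ± 0.09 SE) and Klk7 (-2.23 ± 0.07 SE, base mean 78217) fell most after Krt77, and the late cornified envelope gene Lce1b fell 4.69-fold in the authors' deposited table. The spinous keratins Krt1 and Krt10 fell 2.49-fold and 1.84-fold, the cornified envelope genes Lor 2.42-fold and Ivl 1.52-fold, in the authors' deposited table. Members that rose in the authors' deposited table included the cornified envelope gene Cnfn (2.99-fold), the envelope plakin Ppl (2.09-fold), the keratin Krt78 (1.93-fold), and the differentiation regulators Ovol1 (1.77-fold) and Grhl3 (1.65-fold). Enzymes of the epidermal lipid barrier followed the same side: 10 of 18 fell, 2 rose and 6 did not pass (10 and 3 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00124). In the authors' deposited table the fatty acid elongase Elovl4 fell 1.85-fold and the lipase Lipn 3.73-fold, while Alox12b, a lipoxygenase of the barrier, rose 2.92-fold. Late cornified envelope genes are close paralogs, and reads could be split between them.

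Genes of wounded or stressed keratinocytes were mostly lower with miR-148a. Of 24 tested genes 16 fell, 4 rose and 4 did not pass (17 fell when adjusted over the list alone), with a median 1.64-fold lower (log2 -0.72, adjusted p = 0.00124; -0.48 over genes with a base mean of at least 100). After Mmp13 and Lcn2, the alarmin S100a8 (-2.64 ± 0.10 SE, base mean 10198) and the EGF receptor ligand Areg (-2.27 ± 0.13 SE) fell most in the authors' deposited table. The largest rises were those of the chemokine gene Cxcl5 (3.19-fold) and the defensin gene Defb14 (2.35-fold, base mean 11146) in the authors' deposited table. The wound keratins split: Krt6a rose 1.56-fold and Krt17 1.19-fold, and Krt6b fell 2.28-fold, in the authors' deposited table.

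**Figure D3:**
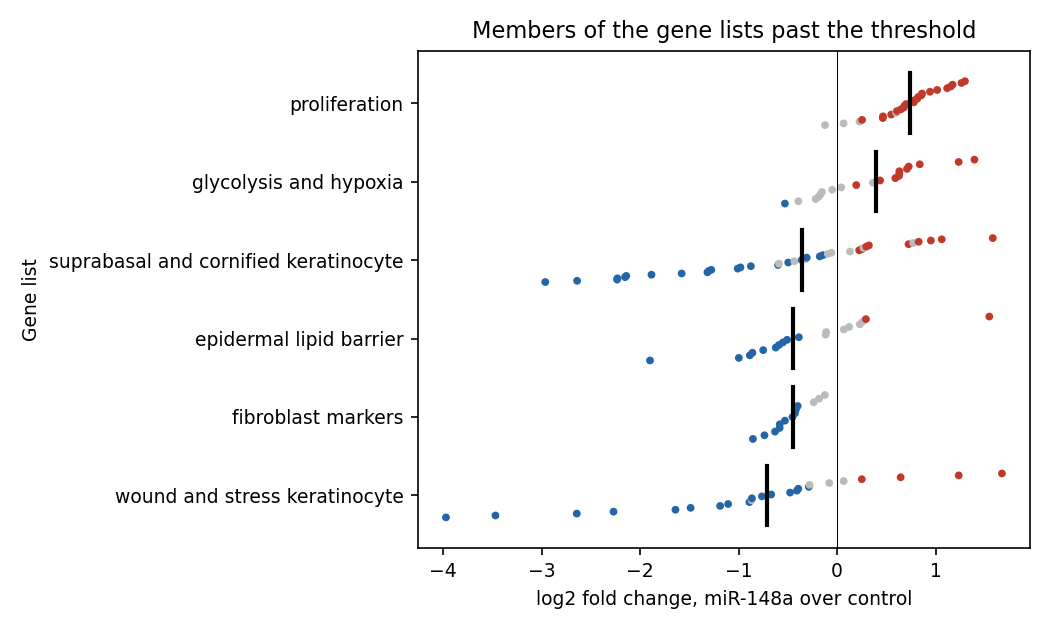
Log2 fold change, miR-148a over control (x axis), of each tested gene in the 6 reported lists whose median passed the test; each point is a gene, red and blue where its adjusted p is under 0.05 and grey where it is not, and the black bar is the list's median. The proliferation list has its median at 0.74 and no blue point, and the wound and stress list has its median at -0.72.

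Markers of other cell types were tested in the same way. Fibroblast markers were lower with miR-148a beside the differentiation and wound lists: 10 of 13 fell, none rose and 3 did not pass (the same counts adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00827). In the authors' deposited table the surface marker Thy1 fell 1.81-fold and the collagen genes Col1a2 and Col1a1, at base means of 6096 and 11119, fell 1.35-fold and 1.34-fold. Of these 13 markers 1 is also in another list. For melanocyte markers 3 of 8 fell and 5 did not pass, with a median of -0.37 (adjusted p = 0.142). For immune markers 3 of 8 fell and 1 rose, with a median of -0.45 (adjusted p = 0.142). Their mean was lower, at -0.87, and the list passed when tested by its mean. The macrophage genes Lyz2 (-2.63 ± 0.34 SE) and C1qa (-2.72 ± 0.39 SE) had base means of only 43.8 and 19.4 in the authors' deposited table. The list of nerve, Schwann and Merkel cell markers held 3 that rose among 10 (median 0.05, adjusted p = 0.649): the keratins Krt8 (5.54-fold) and Krt18 (3.27-fold), which simple epithelia also make, and Mbp (1.88-fold), in the authors' deposited table. Too few endothelial (4), muscle (2) and erythroid (1) markers were tested for a list value. Of the endothelial ones, Kdr and Flt1 rose and Vwf fell.

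Lists of signalling pathways and lineage genes went both ways. The basal keratinocyte list held 4 that rose and 6 that fell among 18: in the authors' deposited table Krt15, a keratin of basal and hair follicle stem cells, rose 3.12-fold (1.64 ± 0.30 SE), Krt5 rose 1.41-fold, and the collagen receptor subunit Itga2 fell 3.76-fold. Its median of -0.24 did not pass over 31 lists (adjusted p = 0.106). Hair follicle stem and progenitor genes split evenly, 5 up and 5 down of 15 (median -0.12, adjusted p = 0.418), with the hair follicle keratin Krt75 among the former and the stem cell receptor gene Lgr5, at a base mean of 40.5, 3.19-fold lower in the authors' deposited table. Of 13 Notch pathway genes 6 fell and 2 rose (median -0.25, adjusted p = 0.0964): the feedback inhibitor Nrarp, with an 8mer, fell 1.86-fold, the ligand Jag1 fell 1.74-fold and the receptor Notch2, with a 7mer-m8, rose 1.43-fold in the authors' deposited table. In the TGF-beta and BMP list 4 rose, among them Id2 and Id3 (2.60-fold), and 5 fell, among them the activin subunit Inhba (2.77-fold), of 26 in the authors' deposited table (median -0.09, adjusted p = 0.444). In the list of small RNA machinery 4 of 13 fell and 1 rose (median -0.10, adjusted p = 0.542): the Argonaute genes Ago4 (1.80-fold) and Ago2 (1.18-fold) and the Argonaute partner Tnrc6c (1.28-fold), each with an 8mer, fell, and Dicer1, with a 7mer-m8, rose 1.31-fold in the authors' deposited table.

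The remaining lists did not pass either, with adjusted p between 0.0964 and 0.972. Counts of genes that rose and fell were 7 and 4 of 24 for p53 targets and cell cycle inhibitors (median 0.20), 5 and 6 of 15 for YAP-TEAD targets (-0.16), 5 and 4 of 25 for ETS and lineage transcription factors (0.10), and 6 and 8 of 22 for Wnt pathway targets (0.06). They were 0 and 2 of 9 for the Hedgehog pathway (-0.33), 3 and 6 of 16 for mesenchymal genes (-0.25), 5 and 6 of 24 for cell junctions (-0.14), and 2 and 3 of 21 for the interferon response (-0.09), which transfected double-stranded RNA can induce. Both groups were transfected with a small RNA, so this comparison cannot show a response to transfection itself. Of the 40 interferon genes listed, 10 were at 0 in every transcript, and some tested ones, such as Ifit1 (base mean 6.60) and Oas1a (11.2), were weakly counted. The counts were 4 and 9 of 27 for cholesterol synthesis (-0.10), 2 and 3 of 12 for DNA methylation and chromatin regulators (0.05), 4 and 10 of 25 for insulin and growth factor signalling (-0.06), and 2 and 8 of 21 for immediate early genes (-0.04). They were 5 and 6 of 16 for the unfolded protein response (0.11), 5 and 2 of 15 for apoptosis regulators (-0.02), and 5 and 3 of 13 for housekeeping genes (0.11). Adjusted over the list alone, the counts were 6 and 7 for YAP-TEAD targets, 7 and 5 for the p53 list, 6 and 4 for the ETS list, 5 and 7 for junctions, 5 and 9 for cholesterol synthesis and 6 and 6 for the unfolded protein response. The other lists that did not pass kept their counts in that adjustment. Means and medians had opposite signs for the hair follicle, Wnt and apoptosis lists. In the authors' deposited table, single genes of these lists with larger changes were the gap junction gene Gjb2 (3.53-fold lower), the transcription factor Atf3 (2.54-fold lower), the ERK phosphatase Dusp6 (2.42-fold lower) and the pro-apoptotic Bax (1.61-fold higher). Mitochondrially encoded genes were not analysed here.

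The authors' deposited GO table held 951 categories, of which 5 passed an adjusted p of 0.05 for over-representation among changed genes. They were the cornified envelope (29 of 47 genes changed, adjusted p = 5.19e-05), structural constituents of the ribosome (28 of 47, adjusted p = 8.58e-05), cytoplasmic translation (14 of 17, adjusted p = 0.00179), the proteasome complex (20 of 38, adjusted p = 0.00179) and assembly of the large ribosomal subunit (13 of 24, adjusted p = 0.0228). The root term molecular function was under-represented (155 of 1422, adjusted p = 8.43e-08). The GO table does not give the direction of the changed genes, and its median category held 2 genes.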

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

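The table has no value per library, so what needs one was not run: other normalizations and pseudocounts, another DESeq2 fit or limma-voom, leaving out libraries, gene set tests with an estimated correlation, and other splits of the 6 libraries. No paired analysis was possible because the columns carry no replicate. The direction of the member genes of each GO category could not be counted without a GO annotation. The count of 3745 changed transcripts fell to 767 (262 higher, 505 lower) with a log2 fold change over 1 in size, and lay between 2901 and 4575 under the 7 other settings. Centring on the median of transcripts with a base mean of at least 1000 (0.05, chosen after seeing the data) gave 1567 higher and 2135 lower. The site difference ran from -0.06 (genes with 1 transcript) to -0.10 (8mer) over 6 alternatives and stayed negative with an interval below 0 in each. The 6 reported lists that passed kept their call and direction with base means of at least 100, with genes of 1 transcript and with means; the last 2 settings were chosen after seeing the data. Sizes moved: with base means of at least 100 the glycolysis and hypoxia median went from 0.40 to 0.61 and the wound list's went from -0.72 to -0.48, above the fibroblast (-0.53) and lipid barrier (-0.51) lists, and the cornified list had a median of -0.36 and a mean of -0.56. The immune marker list passed by its mean (-0.87, adjusted p = 0.00868) and not with genes of 1 transcript (0.112). Lists that did not pass under any setting and changed sign were, with base means of at least 100, hair follicle (0.12), Wnt (-0.11), interferon (0.0166), DNA methylation (-0.0288) and apoptosis (0.0672); with genes of 1 transcript, basal keratinocyte (0.0494), Wnt (-0.31) and apoptosis (0.18); and by the mean, hair follicle (0.0736), Wnt (-0.075) and apoptosis (0.0675). Tnnc2 and Rock2, which did not pass, changed sign, to -0.0092 and -0.0032, after centring on abundant transcripts. The immune and the nerve, Schwann and Merkel lists had too few genes at base means of at least 100. The causes were not tested. The depth of the libraries is unknown, so what it limits was not tested. The median standard error was 0.37 at base means under 100 and 0.08 at 1000 or more.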

Other observations

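Gene families were grouped by symbol after seeing the data, so their counts and medians are descriptions with no test. All 18 late cornified envelope genes that changed fell, of 20 tested, with log2 fold changes from -2.23 to -0.60 in the authors' deposited table and a median 2.94-fold lower. Stefin and cystatin A genes (6 fell of 9, none rose) and the Skint genes, which encode immunoglobulin-like proteins of the epidermis and thymus (4 fell of 6, none rose), had medians 2.95-fold and 2.98-fold lower. Members of both families are close paralogs. Keratins went the other way on balance, 17 higher and 5 lower of 35: Krt19, Krt8, Krt18 and Krt7 (3.29-fold), keratins of simple epithelia, rose in the authors' deposited table together with Krt15 and Krt75, while Krt77, Krt79, Krt1, Krt6b and Krt10 fell. Of 33 proteasome subunit genes 18 rose and none fell (median 1.17-fold higher), and of 64 mitochondrial ribosomal protein genes 24 rose and 5 fell (1.15-fold higher). Collagen genes (14 down and 4 up of 27, median log2 -0.43), serpin B genes (6 down and 2 up of 20, -0.53) and matrix metalloproteinase genes (6 down and 2 up of 13, -0.64) lay lower, and small proline-rich genes went both ways (5 down and 4 up of 13, -0.09). Cytoplasmic ribosomal protein genes were slightly lower, 24 down and 2 up of 72 (median log2 -0.12). Kallikreins lay lower, 6 down and 2 up of 10 (median log2 -0.71), with Klk5 and Klk7 among the lower and Klk10 higher (log2 1.93) at a base mean of 72587 in the authors' deposited table. Arg1, an arginase, rose 4.73-fold at a base mean of 54223 in the authors' deposited table.

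The GO table carries hand-added columns headed as over- and underexpressed. For all 16 terms copied there the values equal the number of changed genes and the number of all genes in the category, so they count no direction. A group headed differentiation (71 and 111) equals the sum of the cornified envelope, structural constituents of the ribosome and cytoplasmic translation. A group headed cell cycle (42 and 212) matches no run of copied terms, whose last 6 add up to 42 and 149.

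In what follows, the test of coding-sequence sites and the test of exonic bases of a transcript's own were set before their results were seen, and the other tests after. Genes with a miR-148a-3p site lay lower with miR-148a. A trend with UTR length, GC content or expression is argued against: after a rank regression on these 3, TGCACTG stood at percentile 100 of 15616 heptamers, first in the negative direction (z = -4.08) and in size, with the overlapping GCACTGA second (-3.71) and the highest z of any heptamer at 3.86. A property of genes that carry the heptamer anywhere is argued against as the whole cause, since 1183 genes with it only in the coding sequence were shifted by -0.02 (-0.0195, interval -0.048 to 0.0091), less than the -0.08 of genes with a 3' UTR site (difference 0.056, interval 0.0098 to 0.0955). These shifts were taken against different reference genes and were not matched on 3' UTR length. Properties of genes that go with UTR length are therefore not covered by this comparison. Repression by the transfected miR-148a is a candidate explanation, with an 8mer shift of -0.12, a 7mer-m8 shift of -0.06 and none resolved for a 6mer, all without matching on UTR length. The sign itself was chosen from this pattern.

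Genes with several transcripts were mostly near 0, among them genes keratinocytes use heavily. All 8 transcripts of Trp63, the master regulator of epidermis, were listed at 0 in the authors' deposited table. Krt14 had 1 transcript at a base mean of 40.3 while its partner Krt5, with 1 transcript in all, had 630448 in the authors' deposited table. Minor transcripts of low abundance are argued against as the whole cause. The sum over all transcripts of a gene had a median of 0.461 in genes with 2 or more transcripts and 3.81 in genes with 1 (ratio 0.121). Reads shared by transcripts of a gene and therefore left uncounted is a candidate explanation: transcripts with no exonic base of their own were at 0 in 98.6% of 2025 cases, against 41.8% of 3473 with 200 bases or more, a ratio of 2.36. Shared reads would not by themselves account for the 40.6% at 0 among 1216 transcripts with 1000 or more bases of their own. Of tested genes, 39.1% with 1 transcript and 14.7% with 2 or more were called changed, and the GO categories may inherit this difference. Elf5 and Dnmt1 would need counts per gene.

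Proliferation genes lay higher with miR-148a. Fewer fibroblasts in the miR-148a cultures would leave a larger share of keratinocytes, and this would raise basal keratinocyte genes as well. These had a median of -0.24 (interval -0.43 to 0.0749) against 0.74 (0.61 to 0.86) for the proliferation genes. Over genes with 1 transcript, only 7 of the 18 basal genes, the basal median changed sign to 0.0494 (-0.35 to 0.49) and still lay below the 0.80 (0.68 to 0.93) of 22 proliferation genes. The basal list as a whole thus did not rise, but on its own it cannot decide the question because its members did not move together. Of the 18, 4 rose and 6 fell: Krt5 (log2 0.49) and Krt15 (1.64) rose and Itga2 (-1.91) fell. Krt14 was read from a weakly counted transcript (base mean 40.3), and so were Itgb4 (4.22), Itga6 (6.50), Itga3 (7.63) and Col17a1 (32.0). A larger share of keratinocytes alone would also raise their differentiation genes. The suprabasal and cornified list instead lay lower (median -0.36, 20 fell and 9 rose of 37), as did the lipid barrier list (-0.45, 10 fell and 2 rose of 18). These values argue against fewer fibroblasts as the only difference between the groups. A part played by fewer fibroblasts in the rise stays open, since 10 of 13 fibroblast markers fell. A change within keratinocytes, another mix of keratinocyte states, and a difference between cultures or batches that happened to follow the groups stay open too, since the table has no value per library. For the lower level of the cornified genes no explanation was tested.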
